A study of Homo sapiens with 4 samples.

How the data were processed

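RNA was measured in EGI-1 cells, a human cholangiocarcinoma (bile duct cancer) line, on 4 whole-transcript microarrays. Per the labels' protocols, the cells were treated for 48 h with CM272 at 200 nM or with vehicle (0.01% DMSO), and the titles number 2 biological replicates in each group. CM272 is a small molecule that inhibits the histone methyltransferase G9a (encoded by EHMT2) and the DNA methyltransferase DNMT1, the targets that the series title names. Per the labels, biotinylated single-stranded cDNA was made from total RNA with a whole-transcript kit. Samples were grouped by the treatment in the labels.

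The deposited table holds 24351 rows with a log2 value per array. Per the submitters' processing notes the tools were RMA and Partek, with no versions or roles given. RMA corrects background, normalizes between arrays and summarises probes, and which of these steps were run here, and the genome build, are not given in the sources used here. The log2 base was inferred from the range of the deposited values, 2.50 to 19.1. Values above 16 exceed the log2 of a 16-bit scanner intensity, so a further rescaling is possible and the size of a fold change depends on it. The array medians of the gene probes were 7.27 and 7.26 for vehicle replicates 1 and 2, and 7.25 and 7.22 for CM272 replicates 1 and 2. The number of arrays limits the precision, and the median negative control value over the arrays was 5.64, which serves as the background level. By array it was 5.78 and 5.74 for vehicle and 5.53 and 5.57 for CM272, so the background differed between the groups.

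Gene names came from the platform annotation. Of 21448 gene probes, 17709 had 1 gene symbol, 0 had several and 3739 had none. All 17709 were matched by Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. That table was used only for names, for the genomic span of genes and for which genes neighbour each other, and no coordinates are given because the files name no build. The 2903 control probes were left out of the test. They comprised 612 negative controls, 2197 positive controls, 63 spike-in probes and 31 others. A gene with several probes (20 genes) was represented in list tests by the probe with the highest mean, which left 17687 genes. Among these 20 genes, probes of CBS, MIA2, PALM2AKAP2 and PRKAR1A differed most in sign or size.

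The comparison used limma 3.58.1 in R 4.3.3. A mean per group was fitted to the 4 arrays with lmFit, followed by eBayes with an intensity trend, with no block. With 2 residual degrees of freedom and a prior of 10.4, the moderated test had 12.4. P values were adjusted by the Benjamini-Hochberg method over the 21448 gene probes, with a threshold of 0.05, and no filter on dim probes was applied. Errors given with a log2 fold change are limma's standard errors (SE), and group means are given with the SD of 2 arrays. Gene lists were tested with limma's camera at its preset inter-gene correlation, adjusted over the 39 lists with 5 or more measured members, beside camera with an estimated correlation and fry. With an estimated correlation camera has only the 2 residual degrees of freedom, so hardly any list could pass. Of 933 distinct genes in the fixed lists, 814 were measured. No probe carried a symbol of the list of mitochondrially encoded transcripts, which was therefore not analysed here.

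Before the data were examined, the lists, the tests, the alternatives and a rule for naming genes were fixed. The rule took, among probes with 1 symbol past the threshold and with no overlap between the groups, the 12 largest rises and the 12 largest falls. It also took EHMT1, EHMT2, DNMT1 and UHRF1, the housekeeping genes ACTB, GAPDH and TBP, and up to 4 called members of each list with the largest absolute change. Where fewer than 2 members of a list passed, the 2 with the largest change were taken as values. Genes named outside the rule are marked as such.

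The alternatives were eBayes without the trend or with a robust prior, an ordinary linear model, removal of the dimmest 25% or 50% of probes, quantile, median and cyclic loess scaling, array weights, the replicate number as a block, each array left out, and other thresholds. A correction for genomic span and mean level was added after the data were seen. Lists were also set against 10000 random lists matched on mean expression, drawn for each member from the 200 genes nearest in level. Lists matched also on genomic span were drawn from the 100 genes nearest in span among the 1000 nearest in level.

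The test was tried on simulated data with the real means and with spreads drawn from limma's own fitted prior, independently for each probe. The rates below therefore hold for data that meet the assumptions of the test. They do not cover genes that vary together or differences between whole arrays. With 200 of the 21448 probes changed, 31.75% of the 2-fold changes and 4.65% of the 1.5-fold changes were recovered, and 5.82% of the calls were false. With 2500 probes changed 2-fold, 83.0% were recovered and 4.50% of the calls were false, and 2 random lists in all were called over 20 simulations of 39 lists. The list matching was tested on 60 simulated lists with a trend in level alone, of which 3 lay outside the middle 95%, and on the same lists with an added shift of 0.4, all 60 of which lay above it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.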

Results

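Gene expression was profiled on 4 whole-transcript arrays of EGI-1 cholangiocarcinoma cells, 2 after 48 h in 200 nM CM272 and 2 after 48 h in vehicle. The series title places the comparison in a study of inhibiting G9a and DNMT1 together in cholangiocarcinoma, and the arrays address which transcripts differed after exposure to the inhibitor. Arrays of the same group correlated at r = 0.994 (vehicle) and r = 0.993 (CM272) over the 21448 gene probes, and arrays of different groups at 0.985 to 0.988. These correlations are across probes, which are not independent replicates. The SD of the difference between arrays was 0.33 log2 units between the vehicle arrays and 0.34 between the CM272 arrays, against 0.46 to 0.51 between groups. The first principal component held 61.8% of the variance and separated the groups, and the second held 19.6%.

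In CM272-treated cells, SCD, SLC7A11, PHGDH and ASNS showed some of the largest falls, and the lists of cholesterol synthesis, fatty acid synthesis and the unfolded protein response were lower by camera at its preset correlation (adjusted p = 0.370, 0.314 and 0.314 with an estimated correlation). The secreted factor IL24, the decoy receptor IL1R2 and the contractile light chain MYL9 rose. The lists of replication-dependent histones and ribosomal proteins were higher by camera at its preset correlation (adjusted p = 0.503 and 0.370 with an estimated correlation), and genes of short genomic span and the array's positive control probes were higher with them. In all, 2579 probes (12.02%) passed limma's adjusted p threshold of 0.05, of which 1211 were higher and 1368 lower in CM272. With array medians subtracted the split turned to 1336 higher and 1236 lower. The 2 arrays of each group did not overlap in any of the 2579, as in 10983 of the 21448 probes tested. Of the called probes, 1938 differed by at least 1.5-fold (877 higher, 1061 lower) and 570 by at least 2-fold (224 higher, 346 lower). Among probes with 1 symbol, 1052 rose and 1134 fell. The count fell to 676 with eBayes without an intensity trend, to 1358 without CM272 replicate 2 and to 1303 at adjusted p under 0.01. The ordinary linear model without moderation called 0 probes after adjustment, with 3146 at an unadjusted p under 0.05. That model has 2 residual degrees of freedom, so hardly any probe could pass adjustment over 21448.

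**Figure D1:**
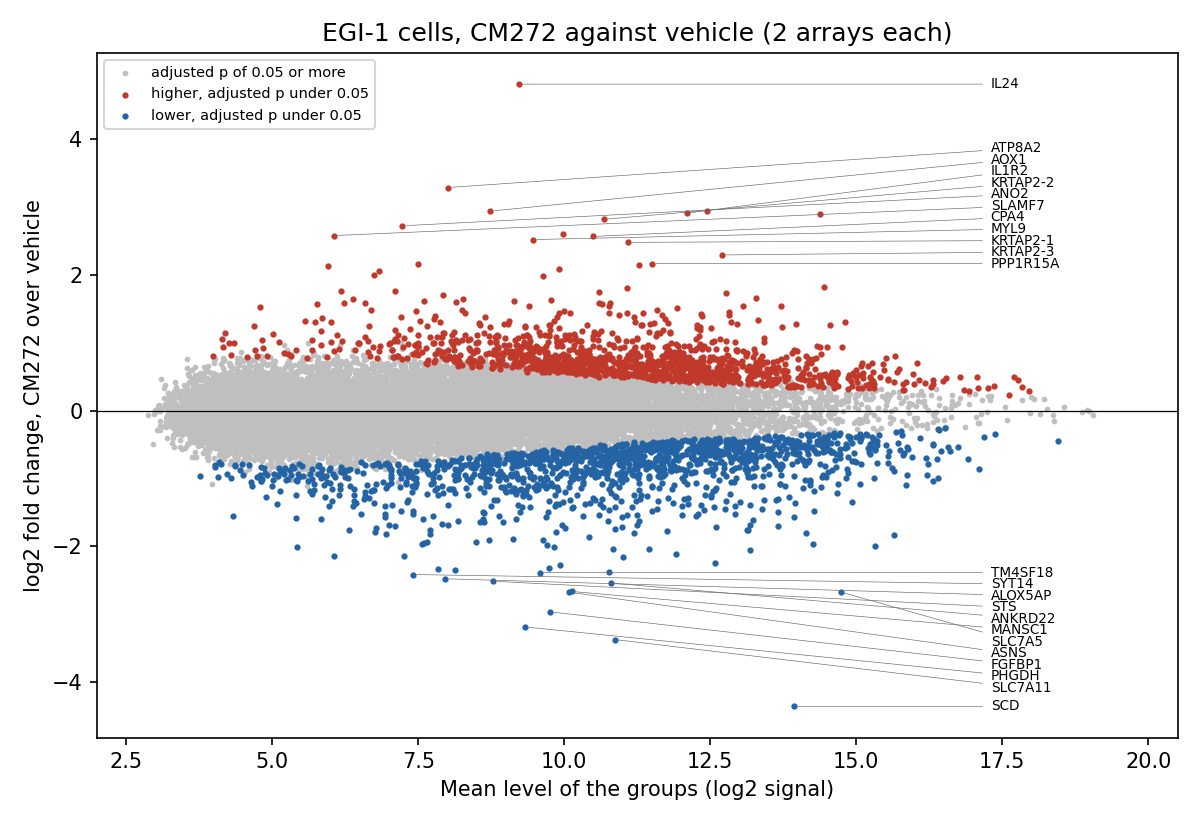
Log2 fold change of CM272 over vehicle (vertical axis) against the mean log2 signal of the groups (horizontal axis) for 21448 gene probes, with the 12 largest rises and 12 largest falls among probes with 1 gene symbol named. Red points are the 1211 probes higher and blue points the 1368 probes lower at limma adjusted p under 0.05, and grey points did not pass.

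IL24, a cytokine of the IL-10 family, showed the largest rise, from 6.81 ± 0.55 to 11.62 ± 0.46 (SD, n = 2 arrays each). Its log2 fold change was 4.82 ± 0.27 (SE), 28.2-fold, with a limma adjusted p of 6.0e-07. ATP8A2, a phospholipid flippase, rose by 3.29 ± 0.20, the aldehyde oxidase AOX1 by 2.94 ± 0.27 and IL1R2, which binds interleukin-1 without signalling, by 2.91 ± 0.17. The keratin-associated protein genes KRTAP2-2, KRTAP2-1 and KRTAP2-3 rose by 2.82, 2.48 and 2.30. These are near-identical copies whose probes may share signal, so their separate values are uncertain. The chloride channel gene ANO2 rose by 2.73, the carboxypeptidase CPA4 by 2.57, MYL9 by 2.52 and PPP1R15A, a phosphatase subunit that acts on eIF2-alpha, by 2.17. SLAMF7, an immune cell receptor, rose by 2.58 from a vehicle level of 4.76, which lay below the median of the negative control probes, so its fold is less certain. The vehicle level of ANO2, 5.86, lay near that median, so the fold of ANO2 is less certain too. Limma adjusted p values of these 12 rises ranged up to 3.9e-05.

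The largest fall was that of SCD, the desaturase that makes monounsaturated fatty acids, from 16.12 ± 0.01 to 11.76 ± 0.90 (SD, n = 2). Its log2 fold change was -4.36 ± 0.27 (SE), 20.6-fold lower, with a limma adjusted p of 1.4e-06. The cystine transporter SLC7A11 fell by 3.38 ± 0.20, PHGDH, the entry enzyme of serine synthesis, by 3.19 ± 0.18, and FGFBP1, a carrier of fibroblast growth factors, had -2.97 ± 0.17. Asparagine synthetase ASNS fell by 2.68 and the amino acid transporter SLC7A5 by 2.67. The remaining falls among the 12 were MANSC1 (-2.67), ANKRD22 (-2.54), the steroid sulfatase STS (-2.52), ALOX5AP (-2.48), which assists leukotriene synthesis, SYT14 (-2.42) and TM4SF18 (-2.39). All 24 genes stayed past the threshold with any single array left out and under each scaling, but 0 of the 24 passed in the ordinary linear model, where their highest adjusted p was 0.301.

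**Figure D2:**
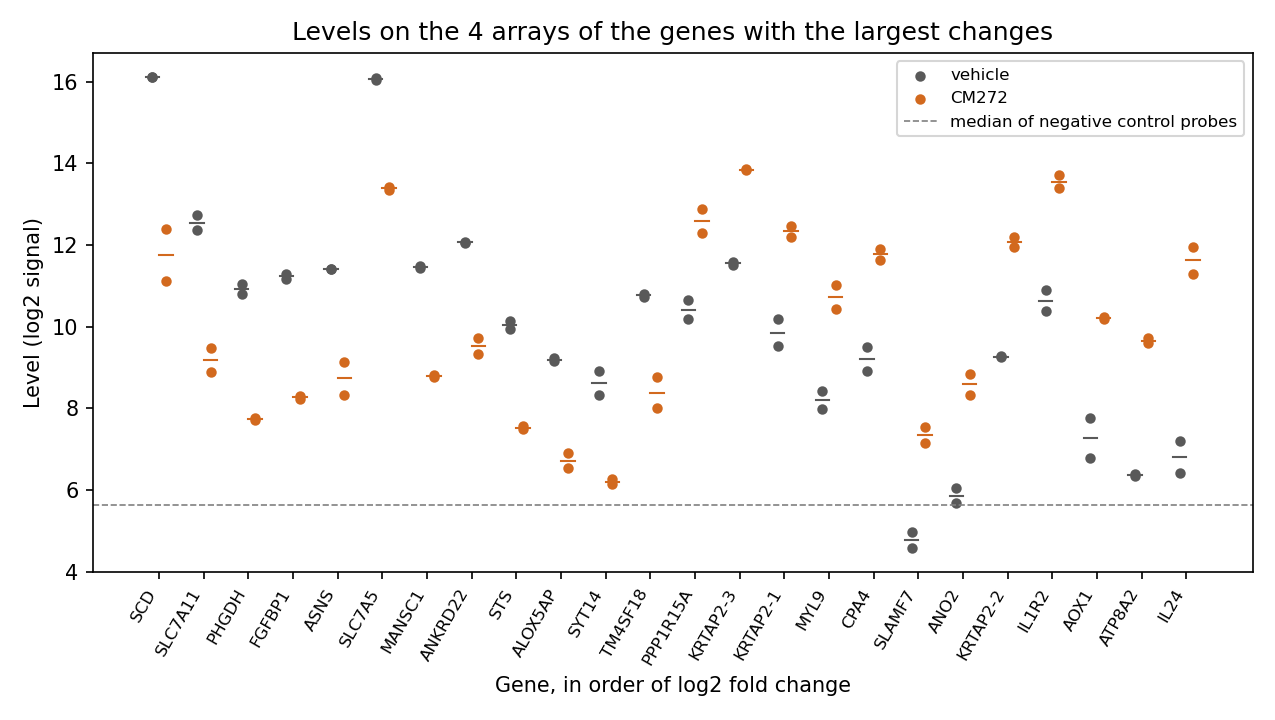
Log2 signal on each array for the 12 largest falls (left) and the 12 largest rises (right), with grey points for the vehicle arrays, orange points for the CM272 arrays and short lines for group means (n = 2). The dashed line is the median of the negative control probes (5.64). The rule that chose the 24 genes required that the groups not overlap.

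The genes encoding the inhibitor's targets did not pass the test. EHMT2 (G9a) had a log2 fold change of -0.41 ± 0.16 (SE, limma adjusted p = 0.138), DNMT1 of -0.32 ± 0.16 (0.258) and its partner UHRF1 of 0.22 ± 0.14 (0.380). EHMT1, the partner methyltransferase of G9a, had -0.25 ± 0.16 (0.378). Transcript levels do not measure the activity of an inhibited enzyme. None of the 8 measured members of the list of drug targets and partners passed, also when adjusted over the list alone (median -0.21, camera adjusted p = 0.625; adjusted p = 0.776 with an estimated correlation). Fry, which asks whether members move on balance one way, gave an adjusted p of 0.0499 for lower values. Of 18 chromatin silencers, the Polycomb methyltransferase EZH2 (-0.58) and the helicase HELLS (-0.56) fell and 0 rose, also adjusted over the list alone, with a camera adjusted p of 0.976. The calls of EZH2 and HELLS were lost without CM272 replicate 2 (limma adjusted p = 0.115 and 0.136), that of EZH2 also without CM272 replicate 1 (0.0501) and that of HELLS without vehicle replicate 1 (0.0762).

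Tests of 39 fixed gene lists placed 9 lower and 6 higher in CM272 at camera's preset correlation and an adjusted p under 0.05. With an estimated correlation 0 of the 39 passed, the lowest adjusted p being 0.314, and with fry 11 passed, 9 of them among these 15. The estimated correlations of fatty acid synthesis and the unfolded protein response were negative (-0.002 and -0.051), yet neither passed. The loss of calls therefore follows largely from the 2 residual degrees of freedom. That setting cannot tell whether correlation between genes accounts for a shift.

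**Figure D3:**
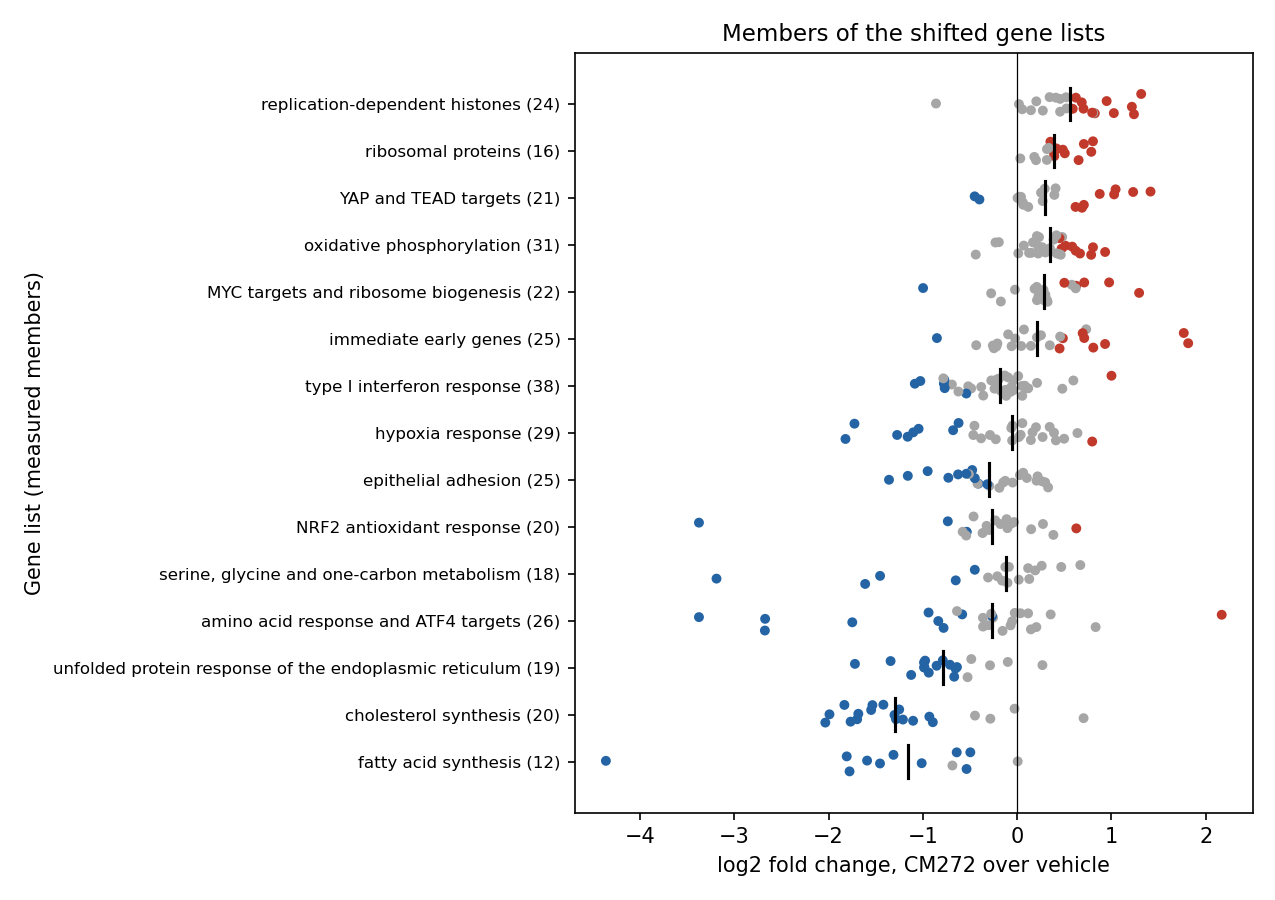
Log2 fold change of CM272 over vehicle (horizontal axis) of each measured member of the 15 gene lists past camera's threshold, with the number of measured members in parentheses. Red and blue points passed limma's threshold as higher or lower, grey points did not, and black lines are list medians, which range from -1.29 for cholesterol synthesis to 0.56 for replication-dependent histones.

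Sterol and fatty acid synthesis showed the largest list shifts. Of 20 measured cholesterol synthesis genes, 16 fell and 0 rose, with a median log2 fold change of -1.29. Adjusted over the list alone, 17 fell and 1 rose. INSIG1, a sterol-regulated retention protein, fell by 2.04 ± 0.17 (SE), and the enzymes DHCR7, MSMO1 and SQLE fell by 1.99, 1.83 and 1.77. The camera adjusted p of this list was 2.5e-21, and adjusted p = 0.370 with an estimated correlation. Of 12 fatty acid synthesis genes, 10 fell and 0 rose, also adjusted over the list alone (median -1.16). SREBF1, which encodes a transcription factor of lipid synthesis, fell by 1.81 ± 0.16, fatty acid synthase FASN by 1.78 ± 0.16 and ACSS2, which makes acetyl-CoA from acetate, by 1.59 ± 0.22, beside SCD. Camera gave 2.0e-12 for it, and adjusted p = 0.314 with an estimated correlation. Fry gave an adjusted p of 0.0469 for each of these lists.

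In the list of the unfolded protein response of the endoplasmic reticulum, 14 of 19 measured genes fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.79. The disulfide isomerase PDIA4 fell by 1.72 ± 0.13 (SE), EDEM1 by 1.34 ± 0.17 and HERPUD1, both of endoplasmic reticulum-associated degradation, by 1.12 ± 0.13. The chaperone HSPA5 (BiP) fell by 0.99 ± 0.08. By camera the adjusted p was 1.5e-15, and adjusted p = 0.314 with an estimated correlation, and fry gave 0.00582.

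In the list of the amino acid response and ATF4 targets, 9 of 26 genes fell and 1 rose (11 and 3 adjusted over the list alone; median -0.27). SLC7A11, ASNS and SLC7A5 led the falls, and PPP1R15A was the gene that rose. The list had a camera adjusted p of 2.9e-04, and adjusted p = 0.370 with an estimated correlation. In the list of serine, glycine and one-carbon metabolism, 5 of 18 fell and 0 rose (6 and 2 adjusted over the list alone). The median of -0.11 lay at percentile 16.93 of lists matched on mean expression, and was -0.00 without vehicle replicate 1 and -0.20 without vehicle replicate 2, where camera's call held. PSAT1, the enzyme after PHGDH in serine synthesis, fell by 1.61 ± 0.11 and the neutral amino acid transporters SLC1A5 and SLC1A4 by 1.45 and 0.65. Camera gave 0.0195, and adjusted p = 0.370 with an estimated correlation, and the call was lost with eBayes without an intensity trend. Of 20 NRF2 antioxidant genes, 4 fell and 1 rose, also adjusted over the list alone (median -0.27). SLC7A11, GSR, which regenerates glutathione (-0.74), and the malic enzyme ME1 (-0.54) fell, and the ferritin light chain FTL rose (0.63). The ME1 call was lost after the correction for genomic span. Camera gave 0.0187, adjusted p = 0.370 with an estimated correlation, and the call was lost with fry (0.0676), without vehicle replicate 2 (0.0937) and without the dimmest 50% of probes (0.0544). The calls of GSR, ME1 and SLC1A4 were lost with an array left out, with limma adjusted p up to 0.199.

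Of 29 hypoxia response genes, 8 fell and 1 rose (9 and 4 adjusted over the list alone), around a median of -0.05. It lay at percentile 25.83 of lists matched on mean expression and 21.17 of lists matched on genomic span too, inside their middle 95%. The median ranged from -0.21 without CM272 replicate 1 to -0.02 without CM272 replicate 2, with -0.18 and -0.13 without vehicle replicates 1 and 2, and camera's call held in each. The falls included LOX (-1.82), which crosslinks collagen, DDIT4 (-1.73), an inhibitor of mTOR that amino acid shortage also induces, the lysyl hydroxylase PLOD2 (-1.27) and the histone demethylase KDM4B (-1.16). Camera gave an adjusted p of 0.0436, adjusted p = 0.370 with an estimated correlation, and the call was lost with eBayes without an intensity trend.

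Epithelial adhesion genes were lower in part. Of 25 measured, 10 fell and 0 rose (12 and 3 adjusted over the list alone; median -0.30). ELF3, an epithelial transcription factor, fell by 1.36 ± 0.24 (SE), the junction protein gene TJP3 by 1.16 ± 0.32, the membrane protease ST14 by 0.95 ± 0.09 and the mucin MUC1 by 0.73 ± 0.18. The CM272 mean of ELF3, 5.75, lay near the negative control median, so the size of its fall is uncertain. The call of TJP3 was lost under quantile normalization, and its CM272 mean of 5.43 lay below the negative control median, so the size of its fall is uncertain. It was -0.60 without CM272 replicate 2 (limma adjusted p = 0.291), and the MUC1 call was lost there (0.159) and without vehicle replicate 2 (0.103). The TJP3 call was also lost without either vehicle replicate (0.0530 and 0.0955). Camera gave an adjusted p of 0.00109, and adjusted p = 0.370 with an estimated correlation. Of 38 type I interferon response genes, 6 fell and 1 rose, also adjusted over the list alone (median -0.18, and -0.32 without vehicle replicate 1). PARP14 fell by 1.09, IFITM1 by 1.03 and USP18 by 0.78, and IFI27 rose from 7.98 to 8.98. The IFI27 change was 0.63 without vehicle replicate 2 (limma adjusted p = 0.116), its call was also lost without CM272 replicate 2 (0.0622), and the USP18 call was lost with any array left out and under quantile normalization. Camera gave 0.00962, adjusted p = 0.469 with an estimated correlation. This call was lost with fry (0.132), without vehicle replicate 2 (0.05003), without CM272 replicate 2 (0.0530) and without the dimmest 50% of probes (0.0544).

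The lists that were higher by camera were ribosomal proteins, oxidative phosphorylation, replication-dependent histones, YAP and TEAD targets, MYC targets and immediate early genes. Of 16 measured ribosomal protein genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.39. RPS4X rose by 0.80 ± 0.11 (SE), RPL6 by 0.79, RPL14 by 0.71 and RPL11 by 0.65. Camera gave an adjusted p of 1.6e-09, and adjusted p = 0.370 with an estimated correlation. Of 31 oxidative phosphorylation genes, 9 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.35). SDHC rose by 0.93, ATP5PO by 0.80, UQCRC1 by 0.78 and NDUFB5 by 0.67, and camera gave 1.0e-06, adjusted p = 0.370 with an estimated correlation. The UQCRC1 change was 0.40 without vehicle replicate 1 (limma adjusted p = 0.210) and its call was also lost without CM272 replicate 2 (0.155). The NDUFB5 call was lost without CM272 replicate 2 (0.104) and without vehicle replicate 2 (0.0575). Of 24 replication-dependent histone genes, 11 rose and 0 fell, with a median of 0.56, and 13 rose and 1 fell adjusted over the list alone. The list mean was 9.04 and 9.44 on the vehicle arrays and 9.67 and 9.91 on the CM272 arrays. The mean change of 0.55 became 0.36 without vehicle replicate 1, where the median was 0.48 and camera's call held. H1-2 rose by 1.32 ± 0.21, H1-4 by 1.24, H2AC8 by 1.22 and H4C8 by 1.03. Histone genes are near-identical copies whose probes may share signal, so single values are uncertain. Camera gave 5.6e-08, adjusted p = 0.503 with an estimated correlation. Genes of short genomic span were higher in CM272 as a class. Among genes brighter than the median, the median log2 fold change was 0.14 in the fifth with the shortest span and -0.10 in the fifth with the longest. The 3 lists had fry adjusted p values of 0.0676 (ribosomal proteins), 0.0676 (oxidative phosphorylation) and 0.211 (histones), and the array's positive control probes were also higher in CM272, by a median of 0.18.

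Of 21 measured YAP and TEAD targets, 8 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.29). ANKRD1 rose by 1.41 ± 0.12 (SE), the kinase NUAK2 by 1.23, AJUBA by 1.04 and RBMS3 by 1.03. Camera gave an adjusted p of 3.9e-05, and adjusted p = 0.370 with an estimated correlation. Of 22 MYC targets and ribosome biogenesis genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.28). Spermidine synthase SRM rose by 1.29 ± 0.18, the ribosome assembly factors MRTO4 and PES1 by 0.98 and 0.71, and the transferrin receptor TFRC fell from 15.32 ± 0.04 to 14.33 ± 0.06 (SD). Camera gave 7.2e-04, adjusted p = 0.370 with an estimated correlation. Of 25 immediate early genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.21). The median lay at percentile 99.12 of lists matched on mean expression, but at 97.27 of lists matched on genomic span too, inside their middle 95%. The median was 0.06 without vehicle replicate 1, where the mean change went from 0.30 to 0.20 (camera adjusted p = 0.0251). The AP-1 subunit JUN rose by 1.81 ± 0.17, the phosphatase DUSP1 by 1.77 ± 0.25 and IER2 by 0.93, and NR4A2 fell by 0.85. Both group means of NR4A2 lay below the negative control median, and its call was lost under quantile normalization. Camera gave 0.00403, adjusted p = 0.503 with an estimated correlation, and the call was lost with fry (0.183). The calls of MRTO4, PES1 and NR4A2 were lost with an array left out, with limma adjusted p up to 0.209.

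The remaining 24 lists did not pass camera, and none of them passed with an estimated correlation. Among inflammatory chemokines and NF-kappaB targets, 8 of 24 fell and 4 rose (9 and 4 adjusted over the list alone; median -0.24, camera adjusted p = 0.131). This list passed camera without CM272 replicate 2 (0.0309) and after the correction for genomic span (0.0294). CXCL1 fell by 1.80 and CXCL3 by 1.59, while IL6 rose by 1.99 ± 0.18 (SE) and IL32 by 1.55. In antigen presentation by MHC class I, 5 of 17 rose and 4 fell, also adjusted over the list alone (median 0.17, camera 0.890). The immunoproteasome subunits PSMB9 and PSMB8 rose by 1.33 and 0.87, and the peptidase ERAP2 and the loading factor TAPBP fell by 1.05 and 0.90. Of 27 biliary differentiation genes, 3 fell (MUC1, SOX4 by 0.69 and CLDN4 by 0.32) and SOX9 rose by 0.51, with 6 and 2 adjusted over the list alone (median -0.19, camera 0.0941). The SOX9 call was lost after the correction for genomic span and the CLDN4 call under median scaling. The calls of MUC1, SOX4, SOX9 and CLDN4 were lost with an array left out, with limma adjusted p up to 0.201. Of 23 hepatocyte genes, 0 passed, also adjusted over the list alone (median -0.02, camera 0.976). The hepatocyte genes with the largest differences were FBP1 (0.48, limma adjusted p = 0.0992) and SERPINA1 (0.37, adjusted p = 0.0978).

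Genes often reported as silenced by DNA methylation did not rise as groups. Of 31 cancer-testis and germline genes, 0 passed, also adjusted over the list alone (median 0.02, camera adjusted p = 0.973). The largest differences were STK31 (-0.71, limma adjusted p = 0.0746) and PAGE5 (0.63, adjusted p = 0.112). The median level of this list, 4.96, lay below the negative control median of 5.64, so low levels were not detectable. Of 30 tumour suppressors known to be silenced by promoter methylation, 0 rose and 3 fell, also adjusted over the list alone (camera 0.946). These were TIMP3 (-1.42 ± 0.14, SE), APC (-0.86) and SPINT2 (-0.61). The median level of the tumour suppressor list, 6.04, lay near the negative control median, so small rises of dim members may have been missed.

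The lists of G1/S, G2/M, p53 targets, apoptosis, senescence, heat shock and lysosome genes did not pass camera. Of 39 G1/S and DNA replication genes, ORC1 (-0.72) and POLA1 (-0.70) fell and 0 rose, also adjusted over the list alone (median 0.01, camera adjusted p = 0.980). Of 40 G2/M and mitosis genes, 4 fell and 2 rose (5 and 4 adjusted over the list alone; median -0.00, camera 0.973), among them CENPF (-0.63), HMMR (-0.58), NUF2 (-0.52) and BUB3 (0.46). The NUF2 call was lost under median scaling. Of 26 p53 targets, 5 fell and 2 rose (5 and 3 adjusted over the list alone; median 0.09, camera 0.973). GDF15 fell by 2.01, FAS by 1.02 and the death receptor TNFRSF10B by 0.81, and GADD45A rose by 1.58. Of 23 apoptosis regulators, 4 rose and 4 fell (4 and 5 adjusted over the list alone; median 0.05, camera 0.973), with PMAIP1 (1.01) and DIABLO (0.82) higher and CASP10 (-1.06) and FAS lower. In cell cycle inhibitors and senescence, 2 of 18 rose (IL6 and IL1B, 0.37) and 2 fell (CXCL8, -0.94, and LMNB1, -0.68), also adjusted over the list alone (median -0.04, camera 0.973). The IL1B call was lost after the correction for genomic span. Of 14 heat shock genes, HSPB1 (1.26) and DNAJB1 (0.67) rose and HSPA1A (-0.93) fell, also adjusted over the list alone (median 0.11, camera 0.388). Of 22 lysosome and autophagy genes, 3 fell (CTSD, -0.83, GLA, -0.72, and CTSA, -0.56) and 2 rose, MAP1LC3B (0.65) among them, with 4 and 3 adjusted over the list alone (median -0.00, camera 0.973). The calls of POLA1, BUB3, HMMR, NUF2, CASP10, DIABLO, DNAJB1, IL1B, GLA and MAP1LC3B were lost with an array left out, with limma adjusted p up to 0.310, and DNAJB1 was 0.44 without CM272 replicate 2.

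Of 21 glycolysis genes, GAPDH (0.35) and PKM (0.34) rose and 0 fell, and 4 rose and 3 fell adjusted over the list alone (median -0.01, camera adjusted p = 0.973). Of 15 drug metabolism and efflux genes, CYP3A5 (-1.49) and CYP1B1 (-1.25) fell and TIPARP (0.49) rose, with 3 and 2 adjusted over the list alone (median 0.06, camera 0.669). The CM272 mean of CYP1B1, 4.79, lay below the negative control median, so the size of its fall is uncertain. Of 15 Notch pathway genes, 0 passed (median -0.07, camera 0.388), the largest differences being HEY1 (-0.61, limma adjusted p = 0.113), below the negative control median in both groups, and MAML2 (-0.48, 0.104). Of 15 Wnt targets, CCND1 rose (0.77) and 0 fell (median 0.05, camera 0.913), and TCF7L2 had -0.63 (limma adjusted p = 0.0662). The Notch and Wnt counts were the same adjusted over the list alone. Of 24 genes of mesenchymal transition, SNAI2 rose (1.01) and 3 fell, MMP14 (-0.86), S100A4 (-0.49) and TGFBI (-0.26), with 4 falls adjusted over the list alone (median 0.02, camera 0.866). The TGFBI call was lost under each scaling and the S100A4 call under median scaling. The calls of PKM, GAPDH, CYP1B1, TIPARP, SNAI2, S100A4 and TGFBI were lost with an array left out, with limma adjusted p up to 0.388.

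Markers of other cell types had median levels of 5.36 (fibroblast), 6.22 (leukocyte) and 6.44 (endothelial), against the negative control median of 5.64, and their counts were the same adjusted over the list alone. Of 15 fibroblast markers, TAGLN, which contractile cells also express, rose by 1.64 ± 0.20 (SE) and 0 fell (median 0.01, camera adjusted p = 0.913), and FBLN1 had -0.31 (limma adjusted p = 0.536). Of 16 leukocyte markers, LAPTM5 fell by 1.29 and 0 rose (median -0.02, camera 0.837), and CSF1R had 0.61 (0.124). Of 12 endothelial markers, CDH5 fell by 1.08 and 0 rose (median -0.26, camera 0.141), and EMCN had 0.66 (0.127), from a vehicle mean of 5.55 below that median. Of 9 housekeeping controls, ACTB (0.65 ± 0.16), GAPDH (0.35 ± 0.08), YWHAZ (0.35) and PPIA (0.33) rose and 0 fell, also adjusted over the list alone (median 0.05, camera 0.119, fry 0.0499). TBP had -0.03 ± 0.20 (limma adjusted p = 0.956). ACTB and GAPDH stayed higher under each scaling, but GAPDH lost its call under quantile normalization, where it was 0.11 (adjusted p = 0.328). The calls of ACTB, GAPDH, YWHAZ, PPIA, CDH5 and LAPTM5 were lost with an array left out, with limma adjusted p up to 0.1497. The housekeeping list passed camera with the replicate number as a block (0.0483). For 10 of the 39 lists, none past the threshold, the median, the mean and camera's direction differed in sign. These were drug metabolism, mesenchymal transition, silenced tumour suppressors, senescence, lysosome, apoptosis, glycolysis, hepatocyte, chromatin silencer and G1/S genes.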

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

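The test of ribosomal protein genes without the other ribosomal protein genes, the trend with genomic span, the correction for it and the tests of span for cholesterol synthesis and the unfolded protein response were chosen after the results were seen. The other tests below were set before their values were seen.

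Positive control probes, which the comparison does not use, were higher in CM272. The difference between the groups' mean array medians was 0.19 log2 units (12.63 and 12.74 on the vehicle arrays, 12.84 and 12.90 on the CM272 arrays), and 72.1% of the 2197 probes were higher in CM272. Which transcripts these probes detect is not given in the sources used here. A brightness-dependent stretch between arrays would also lift gene probes of the same level. The median difference over the positive control probes (0.18) lay at the 100th percentile (100) of 1000 matched sets of gene probes. The middle 95% of those sets ran from -0.02 to 0.02, which argues against a stretch of gene probes at that level. The median of the negative control probes moved the other way. It was 5.78 and 5.74 on the vehicle arrays and 5.53 and 5.57 on the CM272 arrays. Negative controls were not set against matched gene probes, so a stretch at the background level was not tested.

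The lists of ribosomal proteins, oxidative phosphorylation and histones were higher in CM272 at camera's preset correlation (adjusted p = 0.370, 0.370 and 0.503 with an estimated correlation). A stretch with brightness is argued against for all 3, with percentiles of 99.94, 99.94 and 100 among lists matched on level. A shift of short genes is argued against as the whole explanation for oxidative phosphorylation (99.06). Histones lay at 100, but how close their matched genes came to them in span was not tested. The matched lists of histones had a median of 0.135, near the 0.140 of all genes of 57 to 10704 bp brighter than the median. A larger shift of the very shortest genes therefore stays open for histones. Matched members were drawn independently, while histone genes vary together (estimated correlation 0.62, against 0.34 for ribosomal proteins and 0.098 for oxidative phosphorylation). The matched ranges are therefore too narrow, most for histones, and these percentiles overstate the evidence. Ribosomal proteins lay at 92.42 among lists matched on level and span, and at 94.32 with 43 other ribosomal protein genes kept out of the matched lists, so short span may account for their rise. After the correction for span the ribosomal median moved from 0.39 to 0.33 with a camera adjusted p of 1.0e-06, so the correction left that call at the preset correlation in place while the matched lists did not set it apart. An effect of CM272 on these transcripts and a difference in RNA quality between the groups were not tested and stay open.

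Genes of cholesterol synthesis and of the unfolded protein response of the endoplasmic reticulum were lower in CM272 at camera's preset correlation (adjusted p = 0.370 and 0.314 with an estimated correlation). A brightness-dependent stretch between the arrays is argued against for both. Their medians of -1.29 and -0.79 lay at percentile 0 of 10000 lists matched on mean expression. The genomic span of the genes is argued against as well, since both also lay at percentile 0 when matched on span too, and both calls at the preset correlation stayed after the span correction. An effect of CM272 on these pathways stays a hypothesis beside differences in RNA quality or in handling of the cultures, which were not tested.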

How the results depend on the processing

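The correction for genomic span was chosen after seeing the data. The count of 2579 probes called became 676 with eBayes without an intensity trend, 0 in the ordinary linear model (3146 at an unadjusted p under 0.05), 1303 at adjusted p under 0.01, and 1358 to 2239 with an array left out, the lowest without CM272 replicate 2. Fewer samples and the stricter threshold lower the count by construction. The ordinary linear model has 2 degrees of freedom per probe, against 12.4 with moderation, so hardly any probe could pass adjustment. For eBayes without an intensity trend the cause was not tested. The other settings gave 1938 to 3454 probes, with 2461 to 2635 under the scalings. The span correction covers the 17709 probes with 1 symbol and called 2335 of them, against 2322 without it. The split of 1211 higher and 1368 lower turned to 1336 and 1236 with array medians subtracted, 1182 and 1153 after the span correction (1129 and 1193 over the same probes without it) and 1519 and 1503 without the dimmest 50% of probes. A left-out array leaves 1 sample in its group, assumed to vary like the other group. Of the lists, 0 passed with an estimated correlation against 15 with the preset value, and 13 to 15 passed with an array left out. The estimated correlation leaves camera 2 degrees of freedom, so its 0 follows largely from the number of arrays. With fry 11 lists passed, and 15 under each scaling. No called probe, list or named gene changed sign in any setting. Changes of sign without a call occurred for 1 named gene and 15 lists. Of the named genes, 58 lost their call without the trend, and 89 calls of 39 genes were lost over the 4 fits with an array left out, 17 and 20 without vehicle replicates 1 and 2 and 16 and 36 without CM272 replicates 1 and 2. The NF-kappaB list passed after the span correction (camera adjusted p = 0.0294) and without CM272 replicate 2 (0.0309). The span correction ended the calls of SOX9, IL1B, TGFBI and ME1. With the replicate number as a block, 3039 probes and 16 lists passed, the housekeeping list added. The correlation of the replicate differences between the groups was 0.03 over all probes, which gave little sign of a shared batch. On the second principal component replicate 1 lay at -13.0 (vehicle) and -21.3 (CM272) and replicate 2 at 16.6 and 17.7. The 2 replicate differences were of similar size (SD 0.33 and 0.34). With 4 arrays this component therefore follows the sign of that small correlation and is no separate evidence of a batch. No label says that the numbers mark a batch, so a pairing of the samples stays open. Camera was not run with a robust prior or without moderation, which it does not offer. Of the gene probes, 5458 lay below the negative control median on all arrays, where changes are hard to detect.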

Other observations

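The tests of gene families by shared symbol, and the genes named here, were chosen after their values were seen.

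Among 246 families of genes with a shared symbol stem, 23 passed camera's threshold at the preset correlation, and none with an estimated correlation (adjusted p = 0.842 with an estimated correlation). The latter setting again had 2 degrees of freedom, so hardly any family could pass. None of the 23 changed direction under a scaling, and 1, the POLR family, lost its call under cyclic loess (adjusted p = 0.0563). Regulatory subunits of the proteasome (PSMD) had 8 of 12 genes higher and 0 lower, with a median of 0.62, and PSMD4 rose by 1.11 ± 0.16 (SE). Its core subunits (PSMB), 3 of which are in the fixed lists, also had 8 of 12 higher and 0 lower. Mitochondrial ribosomal proteins of the small subunit (MRPS) had 10 of 27 higher and 0 lower, with MRPS18B rising by 1.19 ± 0.13, and those of the large subunit (MRPL) had 10 of 47 higher and 1 lower. Translation initiation factors (EIF) had 16 of 49 higher and 0 lower, EIF6 by 0.94 ± 0.11. Metallothioneins (MT), near-identical copies whose single values are uncertain, had 8 of 13 higher and 0 lower. The families were not matched on genomic span or on mean level. Solute carriers (SLC) had 57 of 363 lower and 9 higher, with -2.25 ± 0.16 for the glutamate transporter SLC1A3 and -1.75 ± 0.18 for the glycine transporter SLC6A9. Clustered protocadherins (PCDHB) had 6 of 16 lower and 0 higher.

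The ligands of the PD-1 receptor were both higher in CM272. CD274 rose from 11.89 to 13.63, by 1.74 ± 0.12 (SE, limma adjusted p = 2.1e-06), and PDCD1LG2 by 1.75 ± 0.16 (2.1e-05). The cytokine IL11 rose by 2.14 ± 0.16 (7.0e-06). The TNF family ligand TNFSF15 fell by 2.04 ± 0.16 (7.3e-06), and the receptors TLR4 and TLR3 fell by 1.68 and 1.55. These calls stayed past the threshold under each scaling.

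All 4 measured KRTAP2 genes rose, KRTAP2-4 by 0.97 ± 0.15 (SE) and the others by more than 2 log2 units. Probes shared between near-identical KRTAP2 copies are a candidate explanation for part of this. Of the 82 other KRTAP genes 0% rose, including 0 of the 39 above the negative control median, as that explanation predicted. A true rise of several KRTAP2 genes alone would give the same count, so it also stays open.

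A hypothesis that neighbouring genes change together, as a spread chromatin change would give, was not borne out at the bound set beforehand. Without pairs that share a symbol stem, 70 neighbouring pairs both rose, against a mean of 55.6 and a middle 95% of 42 to 70 in 10000 shuffles of the calls (one-sided permutation p = 0.0268). For falls the count was 77, against 64.7 and 50 to 80 (one-sided permutation p = 0.0615). Both counts lay above the shuffled mean and neither exceeded the upper bound, so a small excess is not excluded. The shuffles spread the calls over genes of any level, whereas bright probes were called more often. A small excess could therefore not be told apart from bright genes lying next to each other.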
